A study of Mus musculus with 4 samples.

How the data were processed

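Spatial gene expression was measured in formalin-fixed, paraffin-embedded brain sections from mice in which a tumour had been inoculated and resected, with 2 capture areas labelled Vehicle and 2 labelled TREAT, all at day 11. The library chemistry hybridizes pairs of probes to target transcripts, ligates each pair and captures the product on an array of barcoded spots, per the labels' protocols. The authors deposited UMI counts per gene and spot, made with Space Ranger 2.1.1 on the mouse build mm10, with R 4.4.1 and Seurat also named, per the submitters' processing notes. These counts were raw whole numbers with no normalization, and they covered spots over tissue and spots off tissue alike. How tissue was marked is not given in the sources used here. The image scale factors were not used here.

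Of 32589 features, 304 carried an identifier marked as deprecated and were left out of all tests, and 20757 features had counts. The features with counts that were used numbered 20458, of which 20019 matched the gene table of assembly GRCm38.p6 (mm10) by symbol, and gene positions were taken from that table. Only spots over tissue with at least 500 UMIs were kept. Counts were scaled to 10000 per spot and log-transformed, 2000 variable genes and 30 principal components were taken, and spots of all 4 areas were clustered together with the Leiden method at resolution 0.6 on a graph of 15 neighbours (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). No doublet caller was run, since a spot can hold several cells. Clusters were assigned to regions from marker lists written before the data were examined, with at least 3 list members needed among a cluster's 50 leading genes.

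A class was compared by name only where none of its clusters had more markers of another class than of its own among its 10 leading genes. Cluster 12, assigned to the cerebral cortex class, had 1 cortical marker (Lamp5) and 3 meningeal markers (Slc22a6, Ptgds and Fmod) there. The planned comparison over that class is therefore given as clusters 1, 12 and 20 pooled, and clusters 1 and 12 were also tested alone, a choice made after seeing the data. Cluster 13, assigned to the thalamus, failed the same check, and the thalamus was not compared.

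Raw counts were summed per capture area and region, because spots are not replicates, and an area entered a regional test with at least 20 spots. TREAT was compared with Vehicle by edgeR's quasi-likelihood F-test with TMM scaling and filterByExpr (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 values of TREAT over Vehicle with standard errors, and levels are CPM. Differences between the lesion and the pooled clusters were tested as an interaction term with the capture area as a block. Fixed gene lists, 48 in all, were tested with camera (limma 3.58.1) at its preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. Shares of spots carry Wilson 95% intervals, which cover counting error only, and were compared by a two-sided exact permutation test of the area values. Alternatives were DESeq2 1.42.0, limma-trend, other filters on genes and spots, other cluster resolutions, centring per area, the label numbers as a block and leaving out each area. Further alternatives added after seeing the data were library totals as the scaling, the lesion core alone, the lesion with an unnamed cell cycle cluster, and other comparison regions.

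Named genes followed a rule fixed before the data were examined. Per comparison, these were the 12 genes with the smallest p in each direction among those past the threshold whose TREAT areas both lay above or both below the Vehicle areas. With fewer than 6 in a direction, the 6 smallest unadjusted p were given as values. Of each described list, up to 4 members with the smallest p were named. Some genes that the rule chose are not reported here. Genes among the leading genes of a cluster are not counted as results within that cluster.

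The fits were tested on simulated counts with known changes. edgeR recovered 99% of 4-fold and 21% of 2-fold changes over 20234 genes of the whole tissue, 97% and 35% over 19521 genes of the lesion, 99% and 72% over 14021 genes of the pooled clusters, and 63% and 16% over 17231 genes for the interaction. A list of hypoxia genes doubled in the simulated lesion had a camera adjusted p of 4.04e-36 at the preset correlation, 0.244 with an estimated correlation and 0.144 by fry, so those alternatives did not call a doubled list there. In the simulated whole tissue the doubled list had an adjusted p of 0.275 with an estimated correlation and 0.025 by fry. In the simulated pooled clusters these were 0.441 and 0.221. Simulated genes were drawn independently of each other, so these runs cannot tell how the list tests act on genes that vary together.

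The sources state 4 animals for the whole series, while 4 capture areas held 8 separate tissue pieces, 2 per area. Which animals or sections the labels 1+4 and 2+3 join is not given in the sources used here. P-values therefore measure only the spread between capture areas, which may be technical in part. Slide and library batch are not given in the sources used here, so a batch that coincides with the groups is not excluded for any comparison of TREAT with Vehicle.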

Results

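Spatial transcriptomes were recorded from mouse brain sections after tumour inoculation and resection, at day 11, in animals given a hydrogel (TREAT) or not (Vehicle). The design asks how tissue at the site of tumour regrowth differs between these conditions. Each group had 2 capture areas, named Vehicle 1+4, Vehicle 2+3, TREAT 1+4 and TREAT 2+3, and each area carried 2 pieces of tissue. Spots over tissue numbered 3193, 3488, 3352 and 3013 in that order, with 34202695, 45960125, 56150597 and 51081123 UMIs. The median spot was deeper in TREAT, at 14986.5 and 12248 UMIs, than in Vehicle, at 7310 and 8377 UMIs.

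Clustering of all spots together gave regions that were called by their leading genes. The lesion region held clusters 0, 3 and 4. Among their 50 leading genes, cluster 0 had 5 proliferation and 2 mesenchymal glioma markers, and cluster 4 had 3 and 0, with interferon-induced genes such as Gbp2b, its leading gene, Ifi44, Rsad2, Isg15 and Cxcl9. Clusters 0 and 4 formed the core, picked after the clusters were seen by their summed level of proliferation genes (2999 and 2834 CPM). Cluster 3, at 873 CPM and led by genes such as Serpina3n and Pdpn of reactive glia, was called the border. That name rests on its genes alone, since where its spots lie relative to the core was not tested. Cluster 0 was made almost wholly of Vehicle spots (848 and 1157, against 1 and 2 in TREAT), and cluster 4 of TREAT spots (194 and 555, against 0 and 9 in Vehicle). Cluster 3 held spots of both groups (120, 305, 196 and 146). Comparisons within the lesion region are thus largely comparisons of cluster 0 with cluster 4.

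**Figure D1:**
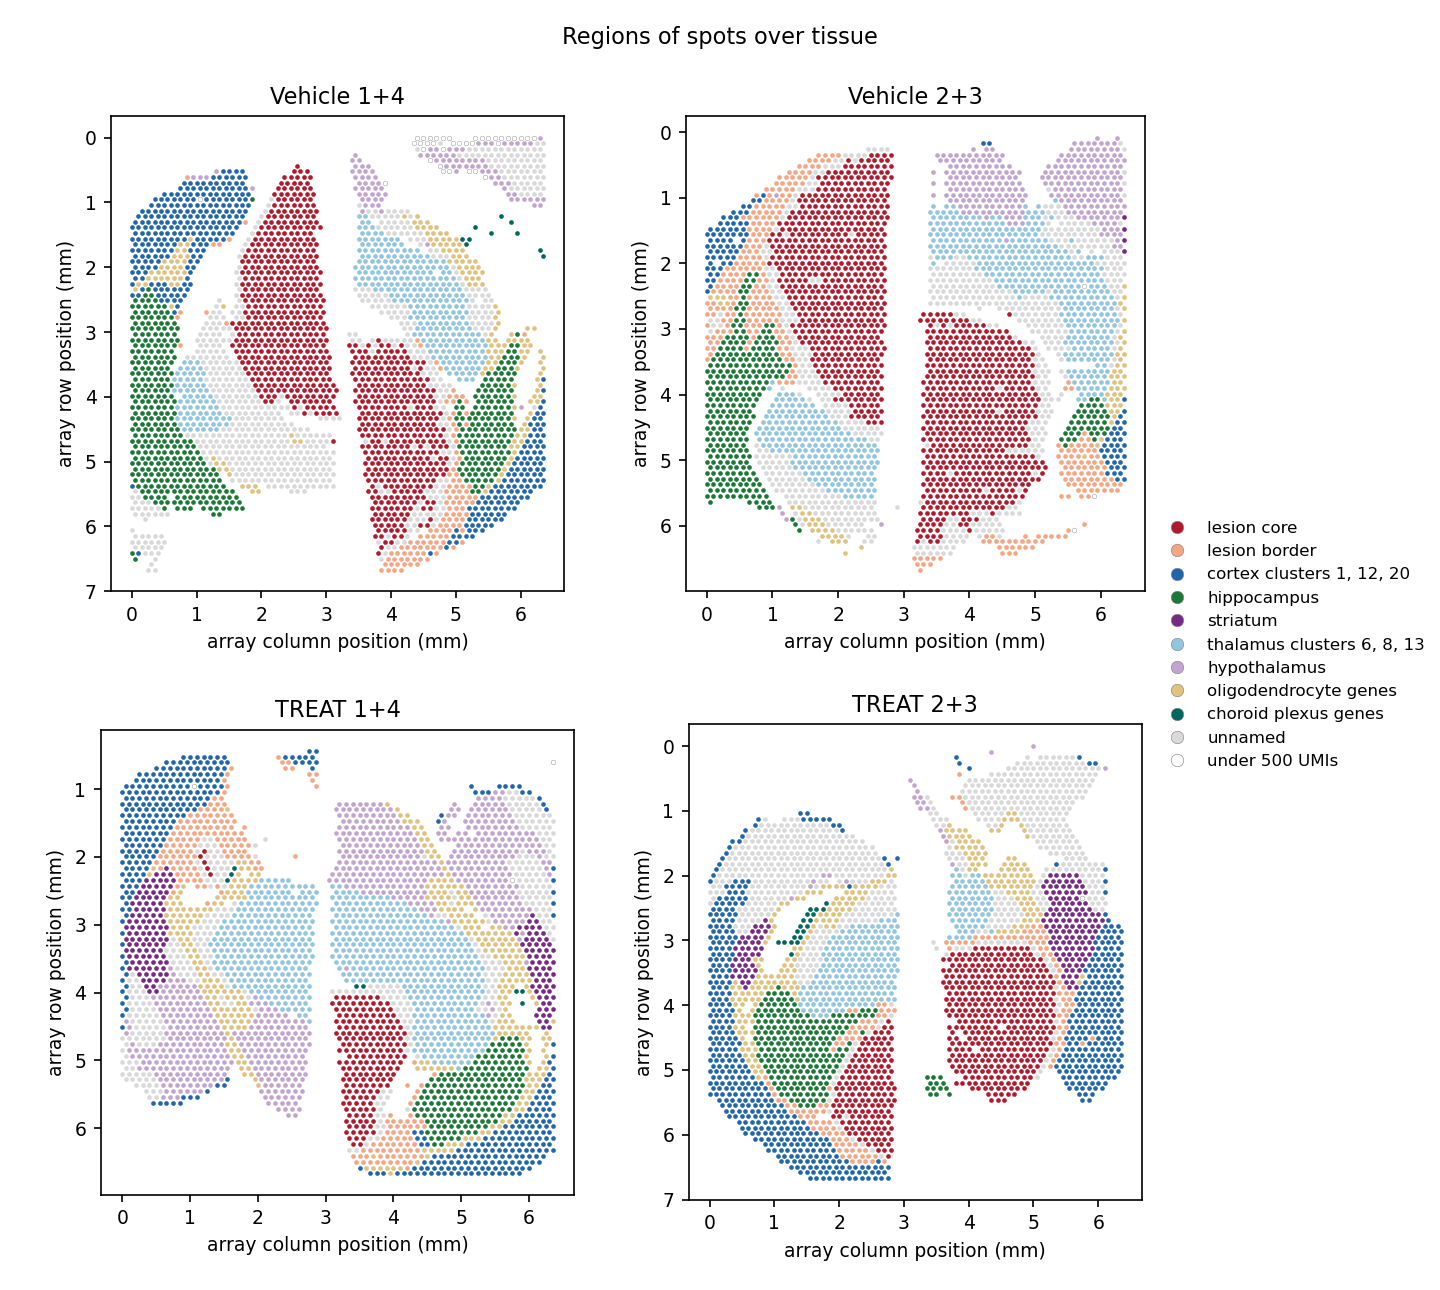
Each spot over tissue is drawn at its array position in mm, coloured by region, with a panel for each of the 4 capture areas. The lesion core takes up more of both Vehicle areas (848 and 1166 spots) than of the TREAT areas (195 and 557 spots).

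The lesion region took up a larger share of spots in both Vehicle areas than in either TREAT area, while striatal spots were found almost only in TREAT. Lesion spots were 30.7% (Wilson 95% interval 29.1 to 32.3) and 42.2% (40.6 to 43.9) of the Vehicle areas, and 11.7% (10.6 to 12.8) and 23.3% (21.9 to 24.9) of the TREAT areas. The means were 36.4% ± 8.17 and 17.5% ± 8.25 (SD, n = 2 each; two-sided exact permutation p = 0.33, the smallest that 6 regroupings allow). The core alone took 30.2% ± 4.67 of Vehicle and 12.2% ± 8.96 of TREAT spots, and the border 6.28% ± 3.50 and 5.35% ± 0.711. In TREAT 1+4 the left piece held 5 core spots among 125 lesion spots, and the right piece 190 among 255. Cluster 10, rich in cell cycle and immunoglobulin genes and left unnamed by the marker threshold, held 5.88% ± 1.91 and 1.82% ± 0.086. Striatal spots were 0 of 3157 in Vehicle 1+4, which allows a share of up to 0.122% (Wilson), and 0.115% of Vehicle 2+3, against 5.20% and 5.54% of the TREAT areas. Spots led by oligodendrocyte and ependymal genes were 3.62% ± 2.40 of Vehicle and 9.17% ± 1.60 of TREAT, and hippocampal spots 12.6% ± 4.69 and 6.71% ± 1.5. The genes that lead these clusters also differed between groups, and the sections passed through different structures, so the shares describe these sections.

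**Figure D2:**
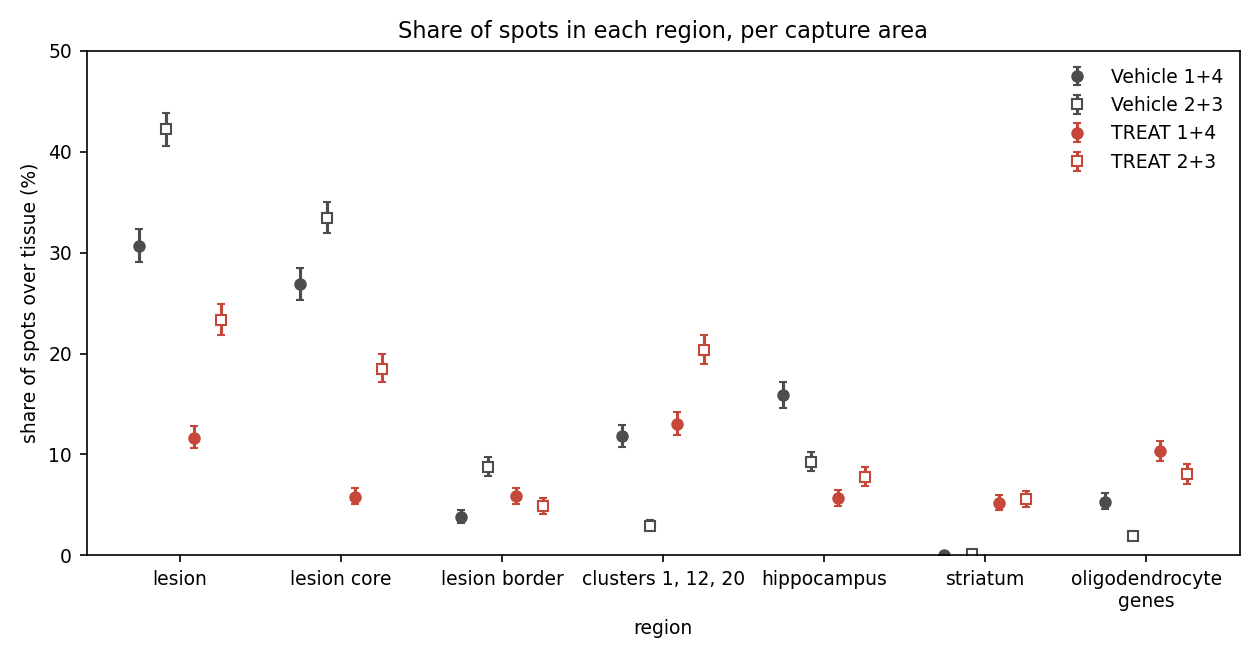
Shares of spots (percent of the spots kept) per capture area are drawn for the lesion, its core and border and other regions, with Wilson 95% intervals as bars. The lesion shares of the Vehicle areas, 30.7% and 42.2%, lie above those of the TREAT areas, 11.7% and 23.3%.

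Over the whole tissue, lists of proliferation, T and NK cell, macrophage and stress response genes were lower in TREAT and striatal genes higher, by camera at its preset correlation, while no list passed with an estimated correlation or by fry. The largest drop by p was in Atf5, a transcription factor of the amino acid and mitochondrial stress response (ENSMUSG00000038539, mm10 chromosome 7, 44812256 to 44816658), which fell by 2.90 ± 0.25 on the log2 scale, from a mean of 188.7 to 25.3 CPM (edgeR adjusted p = 0.0183, n = 2 per group). Penk, the enkephalin precursor of striatal neurons (ENSMUSG00000045573, chromosome 4, 4133536 to 4138815), rose by 3.18 ± 0.33, from 15.4 to 139.4 CPM (edgeR adjusted p = 0.0242). Of 20265 genes tested, 224 were higher and 1149 lower in TREAT at an adjusted p under 0.05. Lesion spots were 36.4% of Vehicle and 17.5% of TREAT spots, as given above, so whole-tissue sums weigh the regions differently in the groups.

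Among the genes that fell with Atf5 were Nkd2, an inhibitor of Wnt signalling (log2 change -2.69), Ngfr, the low-affinity neurotrophin receptor (-2.53), and Ube2c, a ubiquitin-conjugating enzyme of mitosis (-2.60). The cyclin-dependent kinase inhibitor Cdkn2b changed by -2.42, the tartrate-resistant phosphatase Acp5 by -2.36, the granzyme Gzmc by -3.24 and the imprinted gene Phlda2 by -2.33. Pabpc4, a poly(A)-binding protein (-2.47), Mrto4, a ribosome assembly factor (-2.27), Psme2b, which is named for a proteasome activator subunit (-2.06), and Rin3, a Rab5 exchange factor (-2.34), completed the 12 named genes that fell. Psme2b has a near-identical paralogue, so its counts are uncertain. The 12 that rose included Ppp1r1b, the dopamine- and cAMP-regulated phosphoprotein (2.35), the receptor Gpr83 (1.94), the substance P precursor Tac1 (2.07), and the adenosine receptor Adora2a (1.85). The presynaptic complexin Cplx3 rose by 1.74, Nol4 by 1.53, Coch, the cochlin gene, by 1.99, the ciliary gene Cfap206 by 2.12, Ankfn1 by 1.91 and Lnp1 by 2.21.

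Gene lists moved with these genes. By camera at the preset correlation, 26 lists changed, 7 upward and 19 downward. Among genes of at least 10 CPM 18 lists changed, 8 upward and 10 downward. Proliferation genes had a median change of -1.38, with 8 of 21 fallen (14 adjusted over the list alone), among them Rrm2 (-1.96) and Tyms (-2.1), enzymes of nucleotide synthesis, and Cdc20 (-1.59), an activator of the anaphase-promoting complex. The list's camera adjusted p was 4.52e-08, and the adjusted p = 0.641 with an estimated correlation. Mesenchymal glioma genes had a median of -1.30, with 8 of 17 fallen (14 adjusted over the list alone), such as the AP-1 member Fosl1 (-2.20), Emp1 (-1.80), the protease inhibitor Timp1 (-1.65) and the hyaluronan receptor Cd44 (-1.60). Antigen presentation had a median of -1.25, with 4 of 16 fallen (16 adjusted over the list alone), including the class I regulator Nlrc5 (-1.80), the class II regulator Ciita (-1.35), Tapbp (-2.16) and H2-D1 (-1.52). Both lists had a camera adjusted p of 4.58e-07, and an adjusted p = 0.641 with an estimated correlation. Within the lesion region the medians of these 3 lists were nearer 0, at -0.51, -0.61 and -0.53.

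Markers of T and NK cells, of macrophages and of disease-associated microglia were also lower. The last had a median of -0.52, with 2 of 13 fallen (5 adjusted over the list alone). Their camera adjusted p was 0.0118, and the adjusted p = 0.653 with an estimated correlation. Within the lesion region their median was 0.15, which did not pass (camera adjusted p = 0.576). Those of other immune cells did not pass over the whole tissue. Dendritic cells had a median of -0.33, B and plasma cells -0.43, neutrophils 0.09 and homeostatic microglia 0 (camera adjusted p = 0.318, 0.0628, 0.889 and 0.983). Among T and NK cell genes 5 of 12 fell (10 adjusted over the list alone; camera adjusted p = 0.000179, and adjusted p = 0.641 with an estimated correlation, as for the macrophage, stress response, matrix and hypoxia lists that follow), including Cd4 (-1.62), Lck (-1.62), Gzmb (-1.79) and perforin, Prf1 (-1.59). Among macrophage genes 4 of 13 fell (8 adjusted over the list alone; camera adjusted p = 0.00136), including Ms4a7 (-1.56), the mannose receptor Mrc1 (-1.69) and the chemokine receptor Ccr2 (-1.30). Interferon-stimulated genes had a median of -1.0 with 2 of 19 fallen (10 adjusted over the list alone), Ifit3 (-1.15) and Oas1a (-1.60), at a camera adjusted p of 2.82e-06. Within the lesion region T and NK cell, macrophage and interferon genes had medians of -0.37, -0.23 and -0.24, which did not pass (camera adjusted p = 0.299, 0.251 and 0.161), and interferon-induced genes led cluster 4, as given above. Stress response genes had 5 of 13 fallen, with Sesn2 at -1.98, Chac1 at -1.76, Trib3 at -1.74 and Atf4 at -1.33 (camera adjusted p = 0.000709). Matrix and collagen genes had a median of -0.69, with 3 of 21 fallen (8 adjusted over the list alone; camera adjusted p = 0.000396), Thbs2 (-1.60), Lamb1 (-1.37) and Col5a1 (-1.10), while within the lesion region their median was 0.02 (camera adjusted p = 0.214). Hypoxia genes had 2 of 14 fallen (5 adjusted over the list alone; camera adjusted p = 0.0118), the carbonic anhydrase Car9 (-1.44) and the glucose transporter Slc2a1 (-1.24). The interferon list had an adjusted p = 0.653 with an estimated correlation, and none of the 26 passed there.

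The 7 lists that were higher were those of striatal, hypothalamic, cortical, general neuronal, synaptic, oligodendrocyte, and choroid plexus and ependymal genes, while endothelial, meningeal and microglial genes, with medians of -0.66, 0 and 0, did not pass (camera adjusted p = 0.084, 0.994 and 0.983). All 10 striatal genes rose (median 1.92, camera adjusted p = 4.42e-07; adjusted p = 0.641 with an estimated correlation), and striatal spots lay almost only in the TREAT sections, as given above. Synaptic genes had a median of 0.80, with all 16 above 0 and 0 of 16 past the threshold singly (camera adjusted p = 0.000632; adjusted p = 0.653 with an estimated correlation); the scaffold gene Dlg4 had 0.86. Choroid plexus and ependymal genes had 2 of 10 risen (8 adjusted over the list alone), Ccdc153 (1.58) and Enpp2 (1.25), at a camera adjusted p of 0.00167. Oligodendrocyte genes had 1 of 11 risen (5 adjusted over the list alone), Ermn (1.26), at a camera adjusted p of 0.00408, with Opalin at 1.2. With an estimated correlation their adjusted p = 0.641 and adjusted p = 0.653, respectively.

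The whole-tissue calls depended on the test, the scaling, the gene filter and single areas. DESeq2 called 903 higher and 3071 lower, library totals in place of TMM made 81% of 3605 calls higher against 16.3% here and raised the median of all genes by 0.34, a filter at 10 CPM left 0 edgeR calls (4286 at an unadjusted p under 0.05), and without Vehicle 1+4, Vehicle 2+3, TREAT 1+4 or TREAT 2+3 there were 7, 14, 310 and 4770.

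Over the lesion region as a whole, the oligodendrocyte list was higher and the stress response list lower in TREAT by camera at its preset correlation, but no list passed with an estimated correlation or by fry, and in the core alone the oligodendrocyte list did not pass. Atf5 again had the smallest p among genes that fell, by 2.70 ± 0.22 on the log2 scale from 270.5 to 41.8 CPM (edgeR adjusted p = 0.00305, n = 2 per group). Ermn, which encodes the myelin cytoskeletal protein ermin (ENSMUSG00000026830, mm10 chromosome 2, 58045115 to 58052864), rose by 3.00 ± 0.52, from 6.37 to 52.3 CPM (edgeR adjusted p = 0.00668). Il33, an alarmin cytokine of glial nuclei (ENSMUSG00000024810, chromosome 19, 29925113 to 29960718), rose by 2.49 ± 0.43, from 7.92 to 45.2 CPM (edgeR adjusted p = 0.00637). Of 19842 genes tested, 1638 were higher and 2541 lower in TREAT. Of the higher calls, 1153 had a mean under 2 CPM and 309 a mean of 2 to 10 CPM, against 5 and 21 of the lower calls.

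Other named genes that fell in the lesion, all with an edgeR adjusted p of 0.00305, included Cdkn2b (ENSMUSG00000073802, chromosome 4, 89306289 to 89311032), with a log2 change of -2.18. Odc1, the rate-limiting enzyme of polyamine synthesis, changed by -1.65, Mcm4, a subunit of the replicative helicase, by -1.61, and Col9a3, a collagen IX chain, by -1.85. Pabpc4 changed by -1.98, Rin3 by -1.80, the chromatin protein gene Ubn2 by -1.73 and Pex6, a peroxisome biogenesis ATPase, by -1.75. The less studied 2310033P09Rik and 2700081O15Rik had -1.75 and -1.93. Lgals7 was also chosen by the rule, but it leads cluster 0 and is not counted as a result here. Among genes that rose were Ppp1r1b (1.58), the transcription factor Bhlhe40 (1.06), the fatty acid receptor Cd36 (1.46) and transthyretin, Ttr (2.88), an abundant choroid plexus product. Reg3b (3.98), the deiodinase Dio1 (2.03), the elastase Cela3a (2.44), Gm40460 (2.1), the olfactory receptor Olfr211 (2.71) and the vomeronasal receptor Vmn1r60 (2.77) also rose, all from Vehicle means under 1 CPM. Ttr lay beyond every Vehicle piece in only 3 of 4 TREAT pieces.

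**Figure D3:**
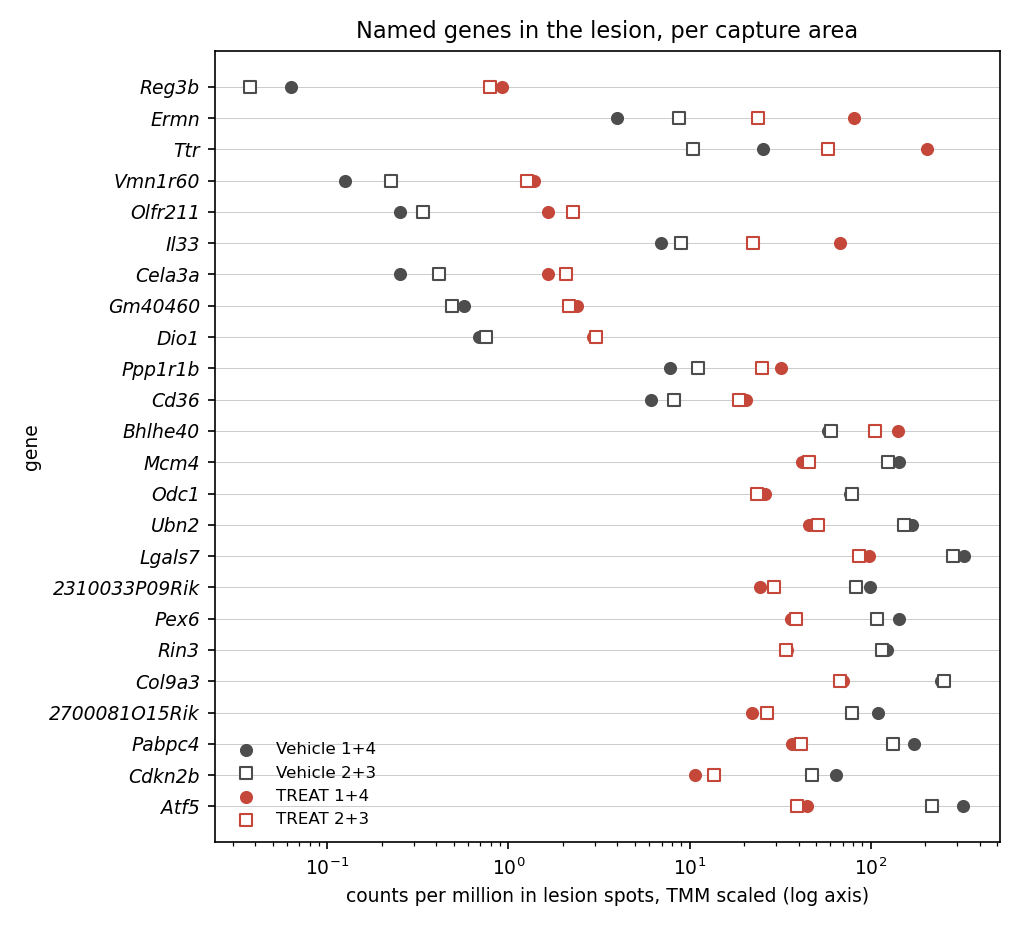
Levels of the named lesion genes are drawn per capture area in CPM on a log axis, with a point for each of the 4 areas. Atf5 lies at 322.4 and 218.5 CPM in Vehicle and at 44.4 and 39.2 CPM in TREAT, and Ermn at 3.96 and 8.77 CPM in Vehicle and at 80.8 and 23.8 CPM in TREAT.

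Of the fixed lists, 2 rose and 6 fell in the lesion by camera. Among genes of at least 10 CPM only the oligodendrocyte list stayed higher and the stress response list lower, and without TREAT 2+3 there were 11 higher and 8 lower. In the core alone, tested after seeing the data, 0 rose and 7 fell, 5 of them among these 6. The exception was proliferation (camera adjusted p = 0.0542), whose genes had been used to pick the core. Also lower were lysosome and lipid genes (median -0.48, 7 of 15 fallen and 2 risen, camera adjusted p = 0.013). So were disease-associated microglia genes (median -0.58, 6 of 13 fallen and 1 risen, camera adjusted p = 0.0186). All 7 had an adjusted p = 0.606 with an estimated correlation. The oligodendrocyte median was 0.62 in the core (camera adjusted p = 0.142). The border held 120 of 968 and 305 of 1471 lesion spots in Vehicle, and 196 of 391 and 146 of 703 in TREAT. Oligodendrocyte genes had a median change of 2.52, and 10 of 11 rose (10 adjusted over the list alone), including the myelin genes Mal (2.75) and Mobp (2.60), at a camera adjusted p of 0.00168. Striatal genes had a median of 1.21, with 5 of 10 risen (8 adjusted over the list alone; camera adjusted p = 0.00417), among them Penk (1.38) and the dopamine receptor Drd2 (1.44). Antigen presentation fell at a camera adjusted p of 0.000197 (median -0.53), with 5 of 16 members fallen (7 adjusted over the list alone), including the peptide loading genes Tapbp (-1.61) and Tap2 (-1.0), with Nlrc5 (-1.02) and H2-D1 (-0.77). Proliferation genes had a median of -0.51, with 9 of 21 fallen (11 adjusted over the list alone; camera adjusted p = 0.00239), including the helicase subunit Mcm5 (-1.02); 5 members of the list lead cluster 0 and 3 lead cluster 4. All 8 lists had an adjusted p = 0.916 with an estimated correlation.

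Mesenchymal glioma genes had a median of -0.61, with 9 of 17 fallen (10 adjusted over the list alone, where 1 also rose; camera adjusted p = 0.00168), including Cebpb, a master regulator of that state (-1.49), Emp1 (-0.89) and the galectin Lgals3 (-0.81). Stress response genes had a median of -0.45, with 6 of 13 fallen (camera adjusted p = 0.00168). Among them were Chac1, a glutathione-degrading enzyme (-1.60), Sesn2 (-1.48) and the endoplasmic reticulum gene Herpud1 (-1.11). The stress response gene Trib3 and some mesenchymal glioma genes are among the leading genes of cluster 0, which is nearly all Vehicle. Immediate early genes had a median of -0.53, with 4 of 13 fallen and 1 risen (5 and 1 adjusted over the list alone; camera adjusted p = 0.00801): Ier2 had -1.63, Nr4a1 -1.62 and Junb -1.24, while Egr4 had 1.45. Hypoxia genes had a median of -0.36, with 6 of 14 fallen (camera adjusted p = 0.0133), including Slc2a1 (-1.42), the mTOR inhibitor Ddit4 (-1.14) and Vegfa (-0.84). For each of these the adjusted p = 0.916 with an estimated correlation, and under library totals, which raised the median of all genes by 0.41, the hypoxia median turned to 0.05 and those of the other 5 fallen lists lay from -0.20 to -0.05.

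Fold changes in the lesion also followed expression level. The median log2 change was 1.04 among 5433 genes with a mean under 2 CPM, 0.46 from 2 to 10 CPM, -0.17 from 10 to 50 CPM, -0.37 from 50 to 200 CPM and -0.50 above. Of 1296 chemosensory receptor genes tested, which are mostly silent in brain, 426 were higher and 0 lower in edgeR. Over all 1442 measured genes of this kind the summed level was 692.4 ± 205.4 CPM in Vehicle and 2123.4 ± 210.7 CPM in TREAT (SD, n = 2 each). Olfr211 and Vmn1r60 belong to these families, whose members are close in sequence.

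**Figure D4:**
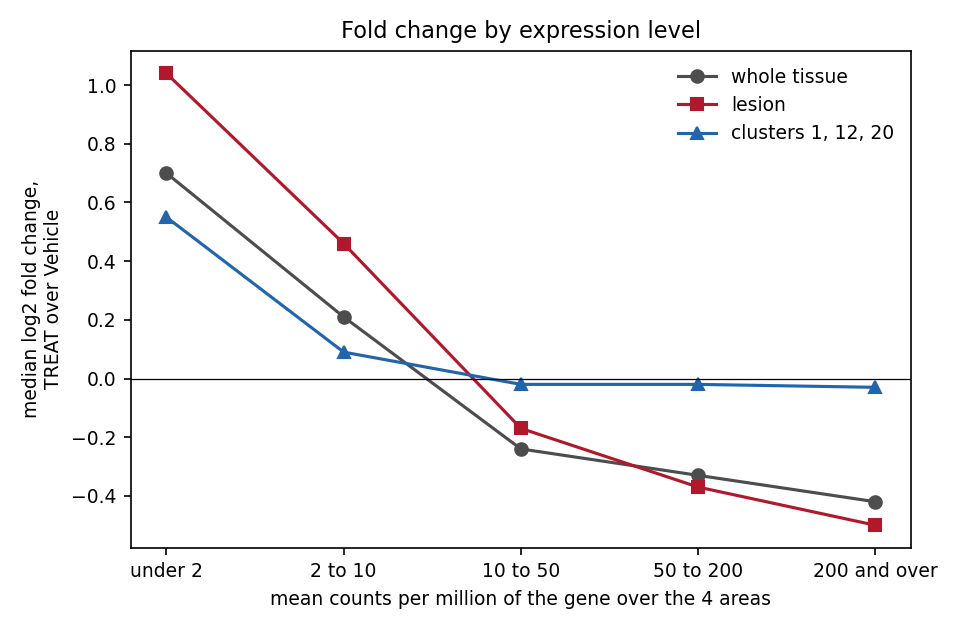
Median log2 changes of TREAT over Vehicle are drawn against bins of mean CPM for the whole tissue, the lesion region and clusters 1, 12 and 20 pooled. The lesion medians run from 1.04 under 2 CPM to -0.50 at 200 CPM and over, and those of the pooled clusters from 0.55 to -0.03.

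The number and balance of the lesion calls depended on the test, the scaling, the gene filter and the Vehicle areas. The share of calls that were higher was 39.2% here, 11.8% of 3416 calls with DESeq2 and 87.3% of 7401 with library totals, which raised the median of all genes by 0.41; calls numbered 753 among genes of at least 10 CPM, 0 with limma-trend, 0 with edgeR without Vehicle 1+4 (7602 and 3917 at an unadjusted p under 0.05) and 346 without Vehicle 2+3.

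In clusters 1, 12 and 20 pooled, regions led by genes of cortical neurons and, in cluster 12, also of the meninges, few genes differed. Pde1b, a calcium- and calmodulin-dependent phosphodiesterase (ENSMUSG00000022489, mm10 chromosome 15, 103503034 to 103530056), fell by 2.18 ± 0.22 on the log2 scale, from 50.6 to 11.4 CPM (edgeR adjusted p = 0.00602, n = 2 per group). It also fell in cluster 1 alone, with a log2 change of -2.33 (edgeR adjusted p = 0.0478), and in cluster 12 alone, with -2.16 (edgeR adjusted p = 0.000738). Of 14292 genes tested, 13 were higher and 7 lower in TREAT.

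The cluster makeup differed, with 149, 58, 268 and 447 spots of cluster 1, 99, 41, 166 and 167 of cluster 12, and 124, 1, 2 and 0 of cluster 20 in Vehicle 1+4, Vehicle 2+3, TREAT 1+4 and TREAT 2+3. Other genes that fell in the pooled clusters were Itm2b, a transmembrane protein that binds the amyloid precursor (-0.96), and Cyp46a1, the cholesterol 24-hydroxylase of neurons (-0.96). The extracellular matrix gene Crtac1 (-0.86), Igfbp5, which binds insulin-like growth factors (-0.76), and the zinc finger gene Rreb1 (-1.25) fell as well. Among genes that rose were the presynaptic genes Rims1 (0.93) and Rph3a (0.92), the G protein subunit Gnb4 (1.36), Nol4 (1.09), the zinc transporter Tmem163 (1.25) and Penk (1.94). Cort, the cortistatin gene, rose by 3.61 on the log2 scale with a Vehicle area at 0. Synpr, a synaptic vesicle gene, rose by 0.92 in the pool but had -0.22 in cluster 12 alone. The rule also chose Cux2, Nr4a2, Cplx3, Ptgds and Gm45623, which are among the leading genes of these clusters and are not counted as results. In cluster 12, Itm2b (-0.87), Penk (1.80) and Rph3a (0.85) passed the threshold too. Of the 19 named genes, 11 lay beyond every Vehicle piece in all 4 TREAT pieces, while Crtac1 and Rreb1 did so in 0 of 4.

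By camera, homeostatic microglial genes fell in the pooled clusters (median -0.43, camera adjusted p = 0.00491), with 0 of 10 past the threshold singly and 2 adjusted over the list alone; Csf1r had -0.67. Meningeal genes rose as a list (median 0.52, camera adjusted p = 0.0155) with 1 of 10 risen, and 3 of that list's genes lead cluster 12. Both had an adjusted p = 0.963 with an estimated correlation. The count of 20 genes became 0 in edgeR with no UMI minimum (1997 at an unadjusted p under 0.05), 1 and 0 at cluster resolutions of 0.3 and 1.0 (1970 for the latter), 3 in cluster 1 alone and 86 in cluster 12 alone; DESeq2 called 26 higher and 85 lower, 23.4% higher against 65% here. Leaving out Vehicle 1+4, Vehicle 2+3, TREAT 1+4 or TREAT 2+3 gave 8, 33, 204 and 199.

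Whether the change in the lesion differed from that in the pooled clusters was tested as an interaction. Atf5 had the smallest p, with a log2 difference of -2.15 ± 0.24, which did not pass (edgeR adjusted p = 0.0707, n = 2 per group). Among the genes with the smallest p below 0 were also the early response gene Ier3 (-2.04), the ubiquitin-conjugating enzyme Cdc34 (-1.54), Nkd2 (-2.83), Col9a3 (-1.66) and Klf16 (-1.63). Above 0 were Ppp1r1b (1.46), Otof (2.31), Hs3st1 (1.97) and Dact2 (1.5). The rule also gave Rnf39, which is among the leading genes of clusters 12 and 20 and is not counted as a result. With edgeR, 0 of 18809 genes passed, 3528 had an unadjusted p under 0.05, and no other tool was run for this term. For the lesion core alone 2088 genes passed, 131 against cluster 1 alone and 149 against cluster 12 alone, and without TREAT 1+4 or TREAT 2+3 there were 1444 and 3186.

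In other regions, the border cluster had 68 genes higher and 136 lower in TREAT by edgeR, and the spots led by oligodendrocyte and ependymal genes had 15 and 56. In the hippocampal spots edgeR called 0 genes, with 2324 at an unadjusted p under 0.05, and DESeq2 called 22 higher and 258 lower. Over all spots outside the lesion and the unnamed cell cycle cluster edgeR called 0, with 4045 at an unadjusted p under 0.05. DESeq2 called 62 higher and 537 lower there.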

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

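The tests of the lesion core alone, of surrounding tissue and of matched expression levels were chosen after the results were seen, and the interaction of gene lists was not among the planned results.

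The difference between groups itself differed between the lesion and clusters 1, 12 and 20 pooled for 10 gene lists, by camera on the interaction term. Oligodendrocyte genes changed more upward in the lesion, with a median difference of 2.18 on the log2 scale (camera adjusted p = 5.41e-07). So did microglial genes (0.94, adjusted p = 6.7e-05), pericyte genes (0.82, adjusted p = 0.00154), astrocyte genes (0.67, adjusted p = 0.0334) and striatal genes (0.36, adjusted p = 0.0334). Immediate early genes changed more downward in the lesion, at -0.79 (adjusted p = 0.00153), as did the stress response (-0.52, adjusted p = 0.00154), nuclear genes of oxidative phosphorylation (-0.34, adjusted p = 0.00174), cholesterol synthesis (-0.45, adjusted p = 0.0334) and hypoxia genes (-0.42, adjusted p = 0.0479). None of the 10 passed with an estimated correlation, where each had an adjusted p = 0.968 with an estimated correlation. Microglial genes were the only one of these lists to pass as lower in the pooled clusters, and in the lesion their median was 0.61 without passing (camera adjusted p = 0.297). In the core alone their median was -0.31 (0 risen, 2 fallen, camera adjusted p = 0.539), nearer the -0.43 of the pooled clusters. Astrocyte genes had 0.04 there, oligodendrocyte genes 0.62, pericyte genes 0.72 and striatal genes 0.90, and none of these passed by camera. The border made up unlike parts of the lesion in the areas, as given above, and its part in these differences was not tested.

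Taking the lesion core in place of the whole lesion, the interaction with the pooled clusters called 214 genes higher and 1874 lower in edgeR, where the whole lesion gave 0.

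A pattern that some of these belong to is that 6 lists fell within the lesion: antigen presentation, mesenchymal glioma, stress response, proliferation, immediate early and hypoxia genes. These are calls of camera at its preset correlation: with an estimated correlation each had an adjusted p = 0.916, none passed by fry, and among genes of at least 10 CPM only the stress response stayed lower. The proliferation, mesenchymal glioma and stress response lists hold genes that lead cluster 0, as given above. More surrounding brain tissue in the TREAT lesion spots stays open. In the core alone 5 of the 6 lists still fell by camera at the preset correlation. Proliferation had a camera adjusted p of 0.0542 there, but the core was picked by that list's genes. Within the core only 1 of 3 marker lists of surrounding cells, oligodendrocytes at 0.62 ± 0.2, lay above 0 by more than 2 standard errors, with neurons at -0.38 ± 0.28 and astrocytes at 0.04 ± 0.23, and many of these genes are near the floor there. Genes enriched in the core fell too, taken against the tissue outside the lesion and the unnamed cell cycle cluster. Their medians were -0.29 to -0.35 under 6 thresholds set after the result had been seen at 4-fold and 10 CPM. The lists had a median of -0.54 ± 0.08 over 94 genes, more than 2 standard errors lower under all 6, but they were chosen because they fell and the enriched genes were not matched on level, so this gap excludes nothing. A fold change that falls with expression level in every gene stays open, because only 1 of the 6 lists, immediate early genes, lay below the lowest 2.5% of 10000 lists matched on mean expression (percentile 1.42). An effect of the treatment may contribute and was not separated from these.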

How the results depend on the processing

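Library totals, the lesion core, the unnamed cell cycle cluster and the single clusters were chosen after seeing the data. So was the filter at 10 CPM for lists and for the interaction. For the interaction, so were leaving out areas and taking all spots outside the lesion for comparison. The other settings were fixed before the data were examined, and the cause of a change was not tested unless stated. When an area is left out, the lone sample of its group is assumed to vary like the other group. Of the named genes, 0 of 285 values changed direction in the whole tissue (80 lost the threshold), 0 of 395 in the lesion (64 lost it), and 6 of 314 in clusters 1, 12 and 20 pooled (146 lost it). The rule had picked these genes from the same areas for small p and separated groups. That choice itself favours few changes of direction, so their small number is no separate support.

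Those 6 were Ptgds, at -0.26 with no UMI minimum, -0.11 at 2000 UMIs, -0.24 at resolution 1.0, -0.54 with centring and 0 in cluster 1 alone, too small there for a direction, and Synpr, at -0.22 in cluster 12 alone. Whole-tissue calls, 1373 in all, became 3974 with DESeq2, 0 at 10 CPM by edgeR (4286 at an unadjusted p under 0.05), 7 with limma-trend, 3605 with library totals and 7 to 4770 without 1 area. Lesion calls, 4179 in all, became 753 at 10 CPM, 0 with limma-trend (7602 at an unadjusted p under 0.05), 9606 with centring, 7401 with library totals, 6416 in the core and 0 to 6048 without 1 area, the 0 being edgeR without Vehicle 1+4 (3917 at an unadjusted p under 0.05). Calls in the pooled clusters, 20 in all, became 111 with DESeq2, 544 with no filter, 0 with no UMI minimum by edgeR, 4 at 2000 UMIs, 0 with limma-trend, 1 and 0 at resolutions 0.3 and 1.0 by edgeR (1997, 1607 and 1970 at an unadjusted p under 0.05 for the counts of 0, in that order), 9 with centring, 3 and 86 in clusters 1 and 12 alone, and 8 to 204 without 1 area.

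Interaction calls, 0 of 18809 by edgeR with 3528 at an unadjusted p under 0.05, became 6735 with centring, 174 with no filter, 2088 for the core, 131 and 149 against clusters 1 and 12 alone, and 0 to 3186 without 1 area. The 26 whole-tissue lists became 0 with an estimated correlation and 0 with fry. The 8 lesion lists, 2 higher and 6 lower, became 0 and 0 by those tests, 13 with no UMI minimum, 2 at 10 CPM, 7 in the core (0 higher and 7 lower, 5 shared) and 11 to 19 without 1 area, the 19 being 11 higher and 8 lower without TREAT 2+3. The 2 lists of the pooled clusters became 0 with an estimated correlation and 1 with fry, which shared 0 with them. The fry call was the list of cortical neurons, lower in TREAT (fry adjusted p = 0.0218), which did not pass by camera (adjusted p = 0.066). By camera it passed as lower in clusters 1 and 12 alone (adjusted p = 0.0314 and 0.0118), though not with an estimated correlation. Genes of that list had been used to assign these clusters. The 2 camera lists became 16 with no UMI minimum (1 shared), 4 in cluster 1 alone (1 shared) and 9 in cluster 12 alone (2 shared). The difference in lesion share, -18.9 points, became -27.3 with centring and kept its direction in all other settings, from -13.1 to -24.8 without 1 area. With centring TREAT 2+3 had 278 lesion and 1282 unnamed spots, against 703 and 744 in the main setting, while lesion spots rose in every other area. The wider gap and the lesion calls with centring rest on that assignment.

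The label numbers are shared between groups, and deviations of same-numbered areas correlated over genes at 0.337 in the whole tissue, -0.02 in the lesion and 0.121 in the pooled clusters, which with 2 pairs does not settle a pairing. With the numbers as a replicate block, gene calls were 9100 in the whole tissue (4749 higher and 4351 lower, 52.2% higher against 16.3%). They were 4541 in the lesion (50% higher against 39.2%) and 548 in the pooled clusters (32.1% higher against 65%). List calls were 27, 11 and 9, in that order. Depth limits low genes most, since a mean under 2 CPM rests on few UMIs in these areas.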

Other observations

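The tests of background signal, of lesion spots of like depth and of section planes were chosen after the results were seen, the one of cell cycle UMIs in thinned spots was set before, and the lesion genes of other groups were chosen after their values were seen, from the members with the smallest p of each list.

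Within the lesion, several genes of other groups moved although their lists did not pass. Of 14 targets of p53, 5 fell (median -0.34), including Cdkn1a, the cell cycle inhibitor p21 (-1.74, edgeR adjusted p = 0.00369), Phlda3 (-1.27, adjusted p = 0.00378) and the pro-apoptotic gene Bax (-0.87, adjusted p = 0.0115). The cathepsin Ctsl fell by 1.13 (edgeR adjusted p = 0.0111) and the lipid droplet gene Plin2 by 0.80 (edgeR adjusted p = 0.0137). Their list, of lysosome and lipid genes, did pass by camera in the core alone, as given above. Of 15 neural progenitor genes 3 fell and 3 rose (median 0.74), with nestin, Nes, at -1.05, Sox4 at -1.11 and Msi1 at -1.23, while Ptprz1 rose by 1.55. Integrin and adhesion genes had 2 of 17 fallen, Itga3 (-1.11) and Zyx (-1.25), and 1 risen, Itgb8 (1.35), with a median of -0.22. Matrix remodelling genes had 3 of 16 fallen, among them Adamts1 (-1.43) and Mmp14 (-0.98), with a median of -0.15. Matrix and collagen genes had 4 of 21 fallen, such as Col5a1 (-1.31), with a median of 0.02. Of 17 hyaluronan genes 2 rose and 0 fell in edgeR (median 0.63), versican, Vcan, at 1.5 and the synthase Has1 at 1.17. Adjusted over the list alone, 5 of these genes rose and 3 fell, and in the core 3 rose and 3 fell. The lesion median lay at percentile 87.2 of lists matched on mean expression.

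Glial, vascular and T and NK cell genes also passed singly in the lesion. Of 12 reactive glial genes (median 0.43) Gfap, the astrocyte filament gene, alone rose, by 1.71 (edgeR adjusted p = 0.0456), and of 10 astrocyte genes (median 0.92) the receptor Ntsr2, by 1.56. Of 9 precursor genes (median 1.03) 2 rose, with Olig1 at 1.38, and Sox10 fell by 0.69. In the core alone the reactive glial median was -0.02 (0 risen, 1 fallen) and the astrocyte median 0.04 (1 risen, 2 fallen). The precursor median was 0.52 there (1 risen, 2 fallen). The border, led by reactive glial genes, made up unlike parts of the lesion in the areas, as given above. Of 9 endothelial genes (median -0.29) 2 fell, with Cldn5 at -0.91, and the transporter Slco1a4 rose by 1.52. Of 12 T and NK cell genes (median -0.37) Lck fell by 0.92 and Gzmb by 1.07, whereas Il2rb rose by 1.47.

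Chemosensory receptor genes were higher in TREAT in the lesion, and a background signal of the whole library is a candidate explanation. Both TREAT areas exceeded both Vehicle areas in 3 of 3 other places. These were the pooled clusters, all spots outside the lesion and the unnamed cell cycle cluster, and spots off the tissue. Off the tissue the summed level of these genes was 1578.3 and 1600.1 CPM in Vehicle and 2715.9 and 2741.6 CPM in TREAT. Deeper spots in TREAT do not account for it alone, because among lesion spots of like depth the TREAT mean was 2.62, 3.0 and 3.23 times the Vehicle mean, at 5000 to 10000, 10000 to 20000 and 20000 to 40000 UMIs, with both TREAT areas above both Vehicle areas in all 3 bins. At 40000 to 80000 UMIs Vehicle 1+4 had only 1 spot, so that bin was not used. Thinning the spots to 5000 UMIs had been set beforehand as the test, but it leaves a share as it was and decides nothing. The ratio varied between regions, from 3.07 in the lesion (3.15 in its core and 1.73 in its border) to 1.69 in the pooled clusters. It was 2.74 in hippocampal spots and 2.38 in spots led by oligodendrocyte and ependymal genes. In all spots outside the lesion and the unnamed cell cycle cluster it was 1.89. A uniform background leaves this spread open, and no biological explanation was tested.

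The smaller share of lesion spots in TREAT may depend on where the sections were taken. How the clusters were drawn and the depth of the spots do not account for it alone: without clusters, and thinned to 2000 UMIs, spots with at least 1 cell cycle UMI were 55.9% ± 10.2 of Vehicle and 32.9% ± 10.9 of TREAT (SD, n = 2 each), a ratio of 0.59. The minimum was not set beforehand, and at 2 and 3 UMIs the ratios were 0.42 and 0.38; 177, 161, 3 and 9 spots were too shallow, and unthinned the shares were 64.8% and 79.3% against 68.5% and 72.1%, which do not separate. Section planes and treatment cannot be told apart here, since 0 of 4 TREAT pieces had a striatum share within the range of the Vehicle pieces (0 to 0.22%, against 2.58% to 9.19%). The lesion share of single pieces ran from 30.9% to 48.6% in Vehicle and from 9.10% to 33.9% in TREAT, so the groups overlapped at that level.

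Genes of the Y chromosome were detected in all 4 areas and were low in the lesion core. Ddx3y had a mean of 7.15 and 9.74 CPM in the core of Vehicle and TREAT. Outside the lesion and the unnamed cell cycle cluster it had 49.5 and 55.4 CPM.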
